A study of Mus musculus with 81 samples.

How the data were processed

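Liver RNA of fasted male mice was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, the mice belonged to the BXD family, inbred lines derived from crosses of C57BL/6J with DBA/2J, and to both parents. They ate a Harlan chow or, from week 8 of age, a Harlan high-fat diet, and were killed at 29 weeks. RNA of about 5 animals of a strain and diet was pooled in equal amounts before 1 array was run. Each of the 81 arrays is therefore a pool. In the paired fits the diet, strain and parental p-values rest on how the diet difference of pools varies between strains, technical spread included. They do not measure the spread between animals. There were 41 chow and 40 high-fat arrays of 42 strains. The 39 strains with both diets (37 BXD strains and both parents) gave 78 paired arrays. BXD50 (high fat only), BXD60 and BXD92a (chow only) entered only the fits on all 81 arrays and the comparison of strain profiles.

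The submitters' processing notes name Affymetrix Expression Console, without a version. The summarisation method, the annotation release and any rescaling are not given in the sources used here. The deposited values are scores: in every column the 35556 probe sets had a mean of 8 and a standard deviation of 2, so each array had been standardised by the authors or an upstream tool. They behave like values on a log scale, but the base is not stated. Differences are therefore given in score units, where 1 unit is 1/2 of the standard deviation of an array's probe sets, and no fold changes are given. The design fixed in advance assumed log2 values; the same limma tests were run on the scores, and the size limit of 0.5 is in score units. The series has a table of values with annotation and a table of values alone. They differed in 0 cells, and every value column was mapped to a sample. Array medians lay between 7.66 and 7.81. The number of arrays limits the precision; array scores carry no counting depth.

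Of the probe sets, 25096 carried 1 gene symbol, 2 carried several and 10458 none. Where a gene had several probe sets, the one with the highest mean over all arrays was kept, which left 21765 genes. For 1747 of these more than 1 probe set existed, and in 228 different probe sets of the gene passed the diet test in opposite directions. Symbols are those of the deposited annotation and some are old. Of the genes, 17961 were current symbols in a RefSeq gene table (assembly GRCm38.p6), 2758 matched 1 gene through a synonym and 1046 did not match; no coordinates were taken from it. Members of families with near-identical transcripts (Cyp2b, Cyp2c, Cyp3a, Saa, Mup, Orm, Serpina and Gst genes) can share probes, so values for single members are uncertain.

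Diet was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 78 paired arrays with strain as a block, for high fat minus chow. The pairing comes from the strain names. The deviations of a strain's chow and high-fat arrays from the diet means correlated over all genes with a median of 0.341, above 0.1 in 37 of 39 strains. Strain was tested by the moderated F-test over the strain terms with diet as a covariate. The parents were compared by the contrast C57BL/6J minus DBA/2J in the same fit, which rests on 2 arrays of each. The spread between strains was compared between diets with limma on the paired difference of absolute deviations from each diet's median. All used Benjamini-Hochberg adjustment over 21765 genes and a threshold of 0.05. The 33 gene lists were fixed before the data were examined, as were the design, the first set of alternatives below and the rule for named genes. Of their 748 entries, 735 were matched. Lists were tested with camera at a preset inter-gene correlation of 0.01, and member counts are given over all genes and adjusted over the list alone. Chosen after seeing the data, the mean of each list per strain was also tested with a sign-flip permutation test (100000 draws, two-sided). It asks whether a list mean differs from 0, not whether a list shifts more than random lists of genes do.

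Genes were named by rule. For diet these were the 15 largest differences in each direction among genes past the threshold with at least 80% of strains in the same direction. For strain these were the 15 smallest p, for the parents the 10 largest differences each way, and for spread the 5 smallest p each way. For each list up to 4 members with the smallest p were named, and members going against it. For values that set 1 strain apart these were the 10 widest gaps. D2hgdh, Dhtkd1, Bckdha, Bckdhb and Cox7a2l were named in every comparison. Genes named outside the rule are said to be so.

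The tests were tested on simulated data with known changes, 50 genes per size among 21765. The diet test recovered 26% of simulated differences of 0.1 units, 96% of 0.25 and 100% of 0.5, with 8% false genes among those called, above the 5% aimed at. The strain test recovered 64% where the strain SD equalled the residual SD. The parental test recovered 48% of differences of 0.5 units and 92% of 1. The spread test recovered 50% where the ratio of SDs was 2 and 94% where it was 3. False genes among those called were 4.32% for strain, 4.49% for the parents and 3.1% for the spread. All 10 simulated lists shifted by 0.15 units were recovered. Their members were simulated without correlation between genes, so this does not cover lists with correlated members, such as interferon response (estimated correlation 0.428).

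Alternatives were median centring, quantile normalization, removal of the dimmest tercile of genes, BXD strains only, array weights, the probe set with the highest variance, no strain block, strain as a random block, a paired Wilcoxon signed-rank test, an estimated inter-gene correlation and leaving out each strain. Alternatives chosen after seeing the data were a test against the level of the negative controls (limma treat), fits without some strains of similar profile (BXD97, BXD80, BXD103 and BXD96, and these with BXD100), fits without doubted arrays, and fits without the strain block or with a random one on the 78 paired arrays. Figures were drawn with matplotlib 3.10.9.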

Results

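Liver transcript levels were measured on 81 arrays from fasted male mice, 41 on chow and 40 on a high-fat diet. Each array held pooled RNA of about 5 animals of 1 strain and diet. The strains were 37 BXD lines with both diets, which each carry a fixed mosaic of the C57BL/6J and DBA/2J genomes, the 2 parents, and 3 lines with 1 diet. The design answers how diet changes liver transcripts across a genetically varied population and how much transcripts differ between strains. Values are scores (mean 8 and SD 2 over the probe sets of each array), and differences are in score units. Xist lay between 5.39 and 6.25 and the Y-linked Ddx3y between 10.1 and 10.9 on all arrays, as male tissue has. Negative-control probe sets had a median of 6.69.

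On the high-fat diet the largest increase was in Cyp2b9, a cytochrome P450 normally higher in female mouse liver, from 9.07 ± 2.12 to 12.1 ± 1.9 (SD, n = 39 strains). It was higher in 36 of 39 strains, by 3.06 ± 0.36 units (SE; limma, adjusted p = 1.64e-09). Its relatives Cyp2b13 and Cyp2a22 rose by 1.60 ± 0.19 and 1.14 ± 0.17. Cidea, a lipid droplet protein, rose by 1.39 ± 0.16 in 37 of 39 strains, and the fatty acid transporter Cd36 by 1.11 ± 0.12 in 36 of 39. The exceptions were the same few strains. BXD44 and BXD61 went the other way for Cyp2b9, Cidea and Cd36, and BXD63 for Cyp2b9 and Cd36. In BXD44 Cyp2b9 was 14.2 on chow and 8.87 on high fat. The cause was not tested. Lcn2, an acute-phase lipocalin, rose by 1.74 ± 0.25, and Saa2, Saa1 and Orm3, plasma proteins of the acute phase, by 1.19 ± 0.27, 0.93 ± 0.25 and 1.06 ± 0.13. D630002G06Rik, described as a putative organic anion transporter, was higher in 39 of 39 strains, by 1.61 ± 0.06, and AB056442 in 38 of 39, by 1.56 ± 0.13. The galectin Lgals1 rose by 1.03 ± 0.14. 9030619P08Rik, Tceal8 and Gm7262 rose by 1.31 ± 0.12, 0.94 ± 0.10 and 0.92 ± 0.09.

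The largest decreases included Csad, the taurine synthesis enzyme cysteine sulfinic acid decarboxylase, at -0.94 ± 0.11 units in 36 of 39 strains (limma, adjusted p = 9.7e-10). Hamp, which encodes the iron hormone hepcidin, fell from 14.1 ± 1.27 to 13.2 ± 1.49, a difference of -0.88 ± 0.18. The drug-metabolising genes Cyp3a11, Cyp3a41a and Cyp2c55 differed by -0.83 ± 0.10, -0.93 ± 0.09 and -0.95 ± 0.12. The pseudogene Serpina4-ps1, Srgap3, Gpr110, Agxt2l1, Ces6 and Moxd1 lay between -1.09 and -0.78, and Moxd1 did not pass without the strain block on all 81 arrays (adjusted p = 0.0503) but did on the 78 paired arrays (0.041). V165-D-J-Cmu, an immunoglobulin mu sequence, and the olfactory receptor Olfr202 were lower in 39 of 39 strains, by -0.99 ± 0.05 and -0.68 ± 0.03. Grm8 and Krt16 differed by -0.68 ± 0.05 and -0.68 ± 0.05. Several of these genes had means below the negative-control median of 6.69. On chow these were Olfr202 (6.25), V165-D-J-Cmu (6.60) and, of the genes that rose, Cyp2b13 (5.64) and AB056442 (6.235). On high fat they were Olfr202 (5.57), V165-D-J-Cmu (5.61), Krt16 (6.47) and Grm8 (6.67). Of the mitochondrial enzymes named in advance, D2hgdh, Dhtkd1, Bckdha and Bckdhb rose by 0.18 ± 0.03, 0.13 ± 0.03, 0.15 ± 0.03 and 0.16 ± 0.02. Dhtkd1 and Bckdhb did not pass without the strain block on all 81 arrays (adjusted p = 0.294 and 0.146) or on the 78 paired arrays (0.29 and 0.162). Cox7a2l differed by -0.05 ± 0.03 and did not pass (adjusted p = 0.137), while its probe set of higher variance did, at -0.24 (adjusted p = 2.76e-08), and so did Cox7a2l without 5 strains similar to others (adjusted p = 0.0466).

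In total 11693 of 21765 genes passed the diet test, 6020 higher and 5673 lower on high fat, but most differences were small. Only 102 were higher and 60 lower by at least 0.5 units. Negative-control probe sets, which are not all blank (90th percentile of their means 8.755), also differed by diet. In a joint adjustment 851 of 5222 passed, against 11322 genes, and 13 differed by at least 0.5. These counts are not like for like, since the median SE was 0.0854 for controls and 0.0339 for genes. The median absolute difference was 0.0965 units for controls and 0.0843 for genes. Net of error, the SD of differences was 0.118 for controls and 0.149 for genes. The largest negative-control difference was 0.641 units. It was exceeded by 60 called genes, and the whole 95% interval, not adjusted over genes, lay beyond it for 24. Of list members described next, those that differ by less lie within the range of the controls. Over all genes 53.7% passed, and counts of list members are to be read beside that share. No batch is named in the labels, so a technical difference between the diets' arrays and an effect of diet of that size cannot be told apart.

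**Figure D1:**
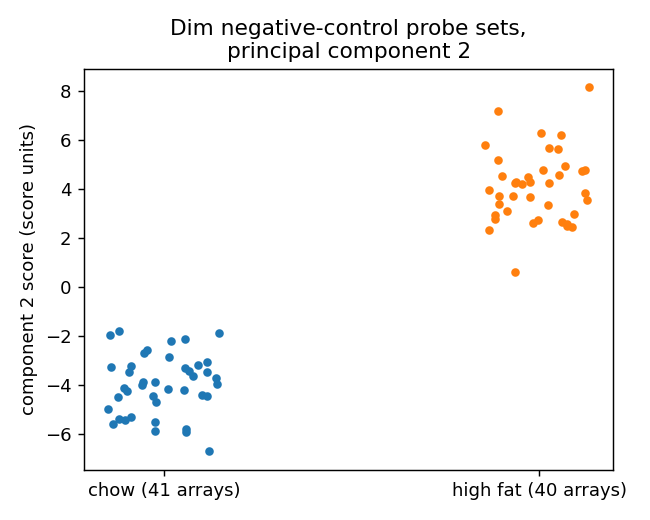
Score of each array on principal component 2 of the 2999 dim negative-control probe sets (score units), 1 point per array by diet. The component was picked among the leading ones for its association with diet. The 41 chow arrays lie at or below -1.79 and the 40 high-fat arrays at or above 0.625.

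**Figure D2:**
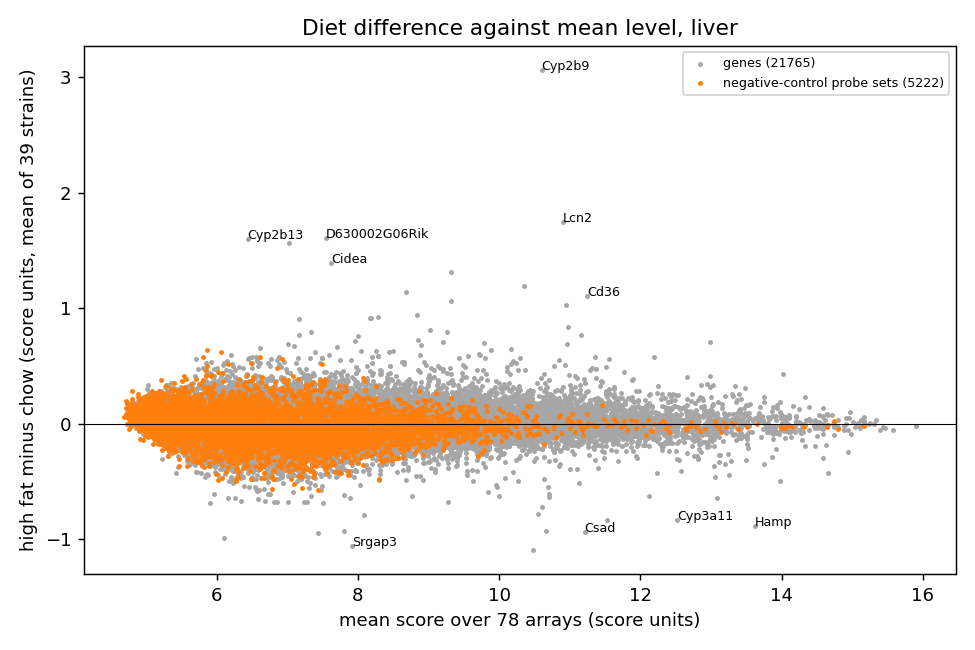
Difference of high fat minus chow (score units, mean of 39 strains) against the mean score of each gene (grey) and each negative-control probe set (orange). Cyp2b9 lies at 3.06, and the orange points reach 0.641.

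Of genes of lipid droplets and lipid uptake, 11 of 22 measured members were higher, 4 lower and 7 did not pass (12 and 4 adjusted over the list alone). Besides Cd36 and Cidea, the lipogenic receptor Pparg rose by 0.54 ± 0.06 units and Fabp2 by 0.39 ± 0.05. Plin5, G0s2, Hsd17b13 and Fitm2 went the other way, at -0.26, -0.32, -0.09 and -0.10. The list mean was 0.253 ± 0.039 (SE over 39 strains), higher in 35 strains (camera, adjusted p = 0.0323; adjusted p = 0.94 with an estimated correlation).

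Interferon response genes showed the most uniform change of the 33 lists, with 21 of 27 higher and 0 lower, also when adjusted over the list alone. Ifi44 rose by 0.71 ± 0.08 units, Dhx58 by 0.50 ± 0.05, Psmb8 by 0.38 ± 0.05 and Mx1, an antiviral GTPase, by 0.31 ± 0.04. The list mean was 0.288 ± 0.042, higher in 36 of 39 strains (camera, adjusted p = 2.48e-07; adjusted p = 0.94 with an estimated correlation). Macrophage and Kupffer cell markers were higher for 15 of 25 members, also adjusted over the list alone, and lower for 2, Cd9 and Cx3cr1 (-0.12 and -0.13). Cd5l rose by 0.36 ± 0.05, Gpnmb by 0.30 ± 0.04, Mmp12 by 0.55 ± 0.10 and Clec4f by 0.25 ± 0.05, with a list mean of 0.151 ± 0.033 (camera, adjusted p = 0.0266; adjusted p = 0.94 with an estimated correlation). Stellate cell and matrix genes were higher for 14 of 25 (16 adjusted over the list alone), among them the collagens Col5a2 (0.32 ± 0.03) and Col3a1 (0.19 ± 0.04), and lower for Des and Loxl1 (-0.13 and -0.13). Their mean was 0.106 ± 0.032 (camera, adjusted p = 0.0266; adjusted p = 0.94 with an estimated correlation). T and natural killer cell markers moved both ways, 5 higher and 7 lower. B and plasma cell markers were 2 higher and 5 lower, with Cd79a at -0.46 ± 0.05. The sign-flip test of the B and plasma cell mean, chosen after seeing the data, called it (adjusted p = 0.00168), but camera did not (adjusted p = 0.516). That mean lay at percentile 12.01 of 10000 random lists, so many of these shifted as far.

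Acute-phase genes were higher for 14 of 25 members (14 adjusted over the list alone), including Steap4 (0.56 ± 0.08 units) and Saa4 (0.35 ± 0.05), and lower for Hamp and Fgg (-0.10 ± 0.02). The list mean was 0.286 ± 0.066 (camera, adjusted p = 0.0323; adjusted p = 0.94 with an estimated correlation). Genes of endoplasmic reticulum stress were higher for 12 of 22 (12 adjusted over the list alone), led by Manf (0.41 ± 0.04), Derl3 (0.31 ± 0.05), Sdf2l1 (0.35 ± 0.07) and Calr (0.18 ± 0.04), and lower for Atf4 (-0.08 ± 0.03), with a mean of 0.111 ± 0.027 (camera, adjusted p = 0.0373; adjusted p = 0.94 with an estimated correlation). The stress list did not pass after median centring (adjusted p = 0.0527) or without any 1 of BXD65, BXD66, BXD73, BXD81, BXD87, BXD90 and BXD100 (0.0516 to 0.0668), with a range of 0.000577 to 0.94 over its alternatives. The acute-phase list did not pass without BXD65 (adjusted p = 0.0511). Without 5 strains similar to others neither list passed (adjusted p = 0.113 and 0.0565).

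Of male-biased liver genes 13 of 20 were lower, 1, Cyp2u1 (0.20 ± 0.06 units), was higher and 6 did not pass (14 and 2 adjusted over the list alone). The major urinary protein Mup20 differed by -0.30 ± 0.05, Elovl3 by -0.64 ± 0.11, Ugt2b38 by -0.31 ± 0.06 and Cyp2d9 by -0.24 ± 0.05. The list mean was -0.246 ± 0.075 (camera, adjusted p = 0.0266; adjusted p = 0.94 with an estimated correlation). Female-biased genes moved apart, 9 of 18 higher and 5 lower: beside the Cyp2b genes A1bg rose by 0.38 ± 0.05, whereas Cyp3a41a, Cyp3a44, Prom1, Fmo2 and Cux2 lay at -0.93, -0.67, -0.19, -0.30 and -0.08. Their mean was 0.33 ± 0.06, higher in 34 of 39 strains (sign-flip test, chosen after seeing the data, adjusted p = 0.00011), but camera did not call them (adjusted p = 0.407). Without the strain block, on 81 arrays, interferon response was the only list called; the adjusted p of the other 6 ranged from 0.121 to 0.21, and on the 78 paired arrays from 0.0722 to 0.14.

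**Figure D3:**
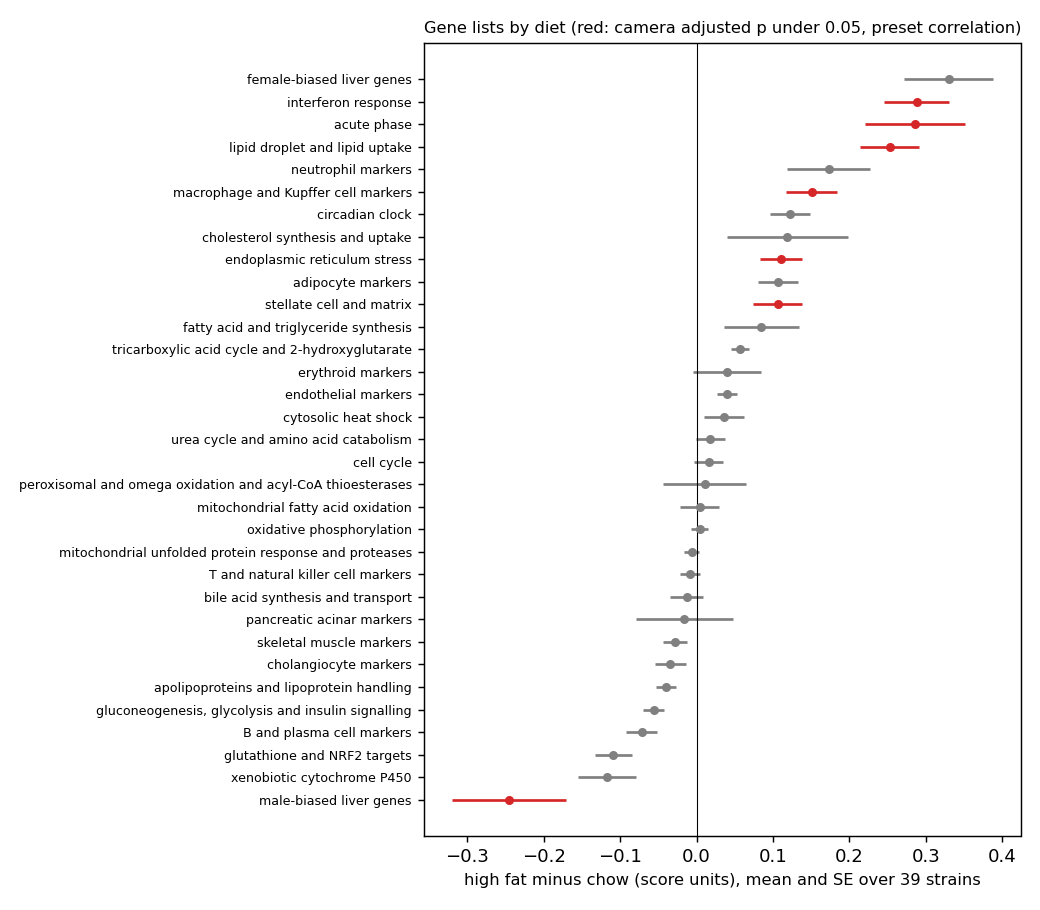
Mean difference of high fat minus chow over the members of each of 33 gene lists (score units, points and bars are mean and SE over 39 strains). The 7 lists past the camera threshold at the preset correlation are red, 6 to the right of 0 and male-biased genes at -0.246.

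Metabolic lists that camera did not call held single genes that changed, where 53.7% of all genes passed the diet test. Some of these lists were called under alternatives. The sign-flip test of list means over strains, chosen after seeing the data, called tricarboxylic acid cycle (adjusted p = 0.00033), glutathione and NRF2 target (0.000577), gluconeogenesis, glycolysis and insulin signalling (0.00084), xenobiotic cytochrome P450 (0.00672) and apolipoprotein genes (0.0071). In the same order, their means lay at percentiles 94.42, 0, 0.74, 0.02 and 7.11 of 10000 random lists. Many random lists thus shifted as far as the tricarboxylic acid cycle and apolipoprotein lists. Of genes of gluconeogenesis, glycolysis and insulin signalling, 5 of 25 were higher and 6 lower: G6pc, the glucose-releasing phosphatase, differed by -0.49 ± 0.05 units and was lower in 37 of 39 strains, Pck1 by -0.35 ± 0.06 and Irs2 by -0.35 ± 0.04. Tricarboxylic acid cycle genes were higher for 13 of 25 and lower for Dlst (camera, adjusted p = 0.0689; 0.043 without the 2 acinar arrays described below, and 0.0427 to 0.0471 without any 1 of BXD43, BXD63, BXD68 and BXD69), with Suclg2 up by 0.25. Cholesterol synthesis genes were higher for 8 of 25 (4 adjusted over the list alone) and lower for Tm7sf2 (-0.19 ± 0.06; camera, adjusted p = 0.176, and 0.0426 without BXD68); Dhcr7 rose by 0.32 ± 0.09. Fatty acid synthesis genes were 7 higher and 2 lower of 23, with Fads2 up by 0.23 ± 0.04 and Scd1 and Me1 at -0.25 ± 0.05 and -0.23 ± 0.07. Mitochondrial fatty acid oxidation had 5 higher and 3 lower of 22, and the 70 genes of oxidative phosphorylation 16 higher and 15 lower (15 and 14 adjusted over the list alone). Xenobiotic cytochrome P450 genes were lower for 12 of 23 and higher for 4 (13 and 5 adjusted over the list alone; camera, adjusted p = 0.281, and 0.0485 without the dimmest tercile), and glutathione and NRF2 target genes lower for 8 of 23 and higher for 3 (8 and 2 adjusted over the list alone; camera, adjusted p = 0.104, and 0.0468 without the dimmest tercile), with Gstp1 at -0.42 ± 0.06 and Gsta2 at -0.53 ± 0.09. Apolipoprotein genes were 4 higher and 7 lower of 22, with Apoa5 at -0.46 ± 0.05. With an estimated correlation camera called none of these lists. Its adjusted p was 0.94 for the tricarboxylic acid cycle, cholesterol, xenobiotic P450 and glutathione lists.

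**Figure D4:**
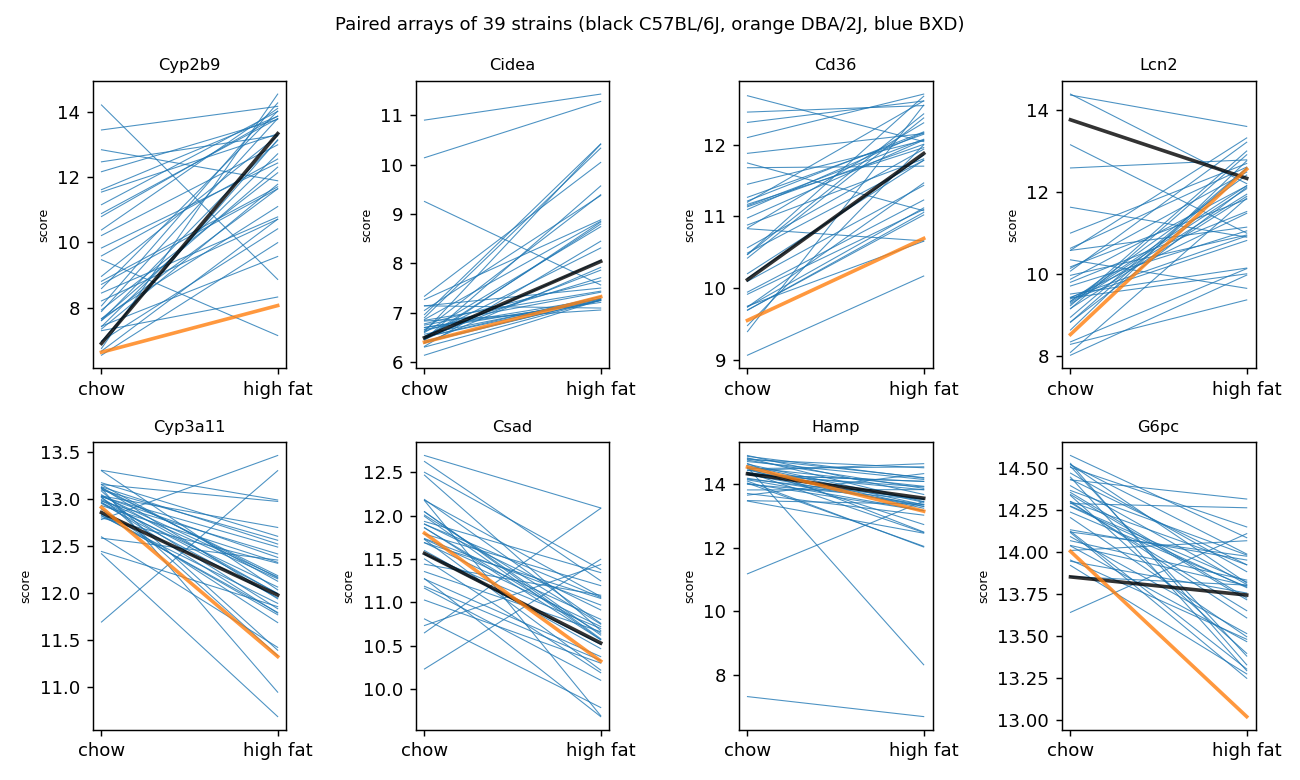
Scores of 8 genes on chow and high fat, each line 1 of 39 strains (C57BL/6J black, DBA/2J orange, BXD blue). Cyp2b9 was higher on high fat in 36 strains and Cyp3a11 lower in 37. BXD44, BXD61 and BXD63 went the other way for Cyp2b9, Cd36 and Csad, and BXD44 and BXD63 for Cyp3a11.

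Strains differed in 4857 genes (limma moderated F-test, adjusted over 21765 genes). Many of the strongest fell into separate levels on both diets. Ctse, the protease cathepsin E, ranged from 7.32 to 13.4 over strain means, with 26 strains at or below 8.45 and 13 at or above 11.8; strain accounted for 97.8% of the variance around the diet means. H2-Ea, a class II antigen chain of the major histocompatibility complex, had 25 strains at or below 6.75 (C57BL/6J among them) and 14 at or above 9.59 (DBA/2J among them). Corin, a serine protease, had 7 strains including C57BL/6J at or below 8.45 and 32 including DBA/2J above them, by a gap of 1.58. For Hc, the complement component C5, 15 strains including DBA/2J lay at or below 13.0 and 24 including C57BL/6J at or above 13.5. C530030P08Rik had a strain share of 99%. The other 10 of the 15 genes with the smallest p were 4933409K07Rik, Sfi1, Snrnp25, Pttg1, Stab2, Ocel1, Cpamd8, Rassf4, Abca3 and EG665955, with strain shares of 94.2% to 97.8%. Bckdhb, Dhtkd1, Cox7a2l and D2hgdh also differed between strains, with strain shares of 94.7%, 89.4%, 77.8% and 62.3%, but Bckdha did not pass (adjusted p = 0.176).

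Over all genes the median strain share was 19.6%, and it exceeded 50% in 1803. Among lists, 26 of 27 interferon genes, 19 of 22 endoplasmic reticulum stress genes, 21 of 25 macrophage genes, 17 of 23 glutathione and NRF2 target genes and 12 of 17 heat shock genes passed the strain test. With 1 pool per strain and diet, differences in age, cage or pooling between cohorts of a strain are not separated from genotype.

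**Figure D5:**
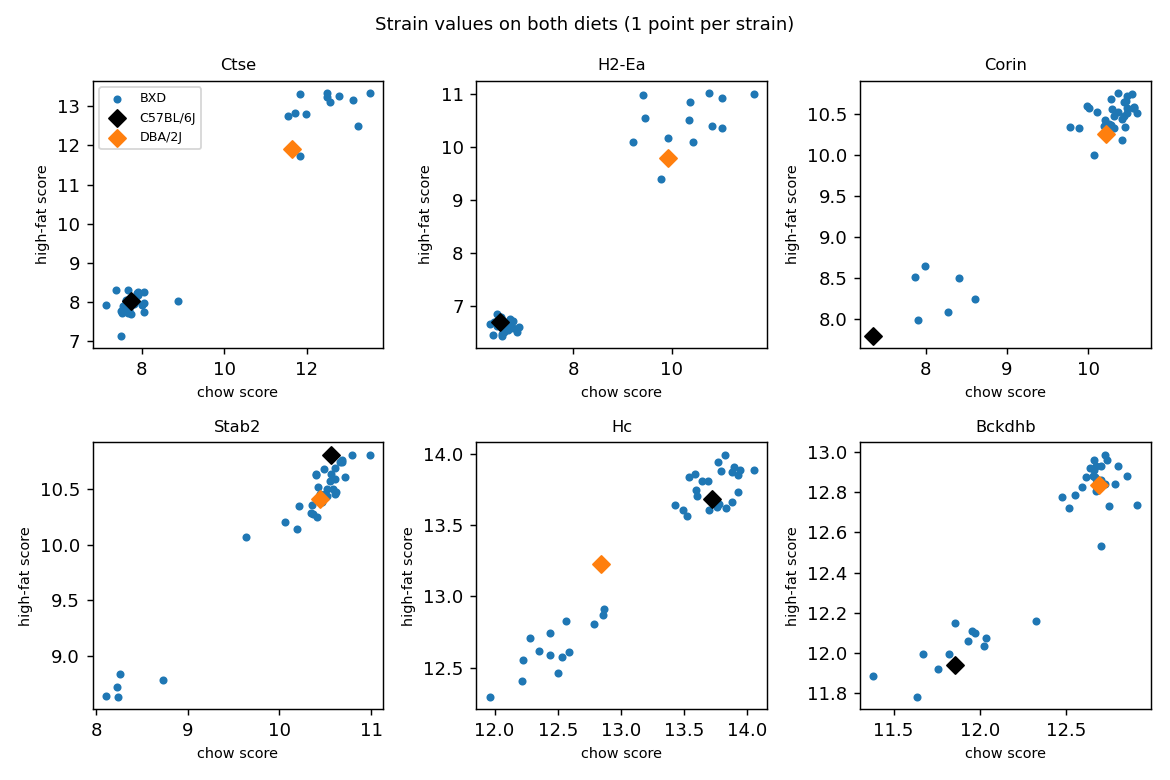
High-fat against chow score for 6 genes, 1 point per strain (C57BL/6J black and DBA/2J orange diamonds, BXD blue). Ctse splits into 26 strains near C57BL/6J and 13 near DBA/2J; 5 BXD strains form a low group for Stab2 without either parent.

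Between the parents 520 genes passed, 294 higher and 226 lower in C57BL/6J; 249 and 177 differed by at least 0.5 units. With array weights 1064 passed, 578 higher and 486 lower, and 642 differed by at least 0.5. Lcn13, a lipocalin, was 8.97 in C57BL/6J and 13.7 in DBA/2J, a difference of -4.72 ± 0.71 (SE; 2 arrays each). Ear11, an eosinophil-associated ribonuclease, Ctse and H2-Ea differed by -4.01, -3.90 and -3.25. EG665955, an endogenous viral envelope sequence, and Rassf4 differed by -3.84 and -3.52. Corin, Ntrk2, Snord53 and Ccr3 lay between -2.66 and -1.82. C530030P08Rik (3.64 ± 0.16), the alcohol dehydrogenase pseudogene Adh6-ps1 (3.37 ± 0.38), E430024C06Rik, Nnmt, Trim12, Cyp2c38, B930036N10Rik, Cyp39a1, 4933409K07Rik and Folr2 were higher in C57BL/6J, by 2.17 to 3.64. Bckdhb and Dhtkd1 were lower in C57BL/6J (-0.87 ± 0.11 and -0.90 ± 0.15). D2hgdh, Bckdha and Cox7a2l did not pass (adjusted p of 0.666 to 0.895).

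Of the 520 genes, 457 (87.9%) also passed the strain test in the BXD strains alone, against 17.3% of the other genes. The DBA/2J chow array and the BXD63 high-fat array held pancreatic acinar transcripts: 16 and 17 of 19 markers were above their level on all 79 other arrays, with Cpa1 at 10.4 and 11.1 against a median of 7.47. Without these arrays DBA/2J is left with 1 array and the contrast is less precise, so a lost call is not in itself a sign of acinar transcripts. The difference was then 1.92 units for Nnmt, against 2.80 with all arrays, and 2.44 for B930036N10Rik, against 2.58. Neither kept its call. Nnmt was 8.31 on the DBA/2J chow array and 10.5 on the DBA/2J high-fat array. Of the acinar markers 4 were among the 520 genes.

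The spread between strains differed by diet in 2 genes. Cyp2b13 varied more on high fat, with an SD of 0.584 on chow and 1.26 on high fat (limma, adjusted p = 0.0126). Its mean rose from 5.64 on chow, below the negative-control median of 6.69, to 7.24 on high fat. A chow SD narrowed by low signal is therefore not excluded. Rtn4 varied less on high fat (limma, adjusted p = 0.0399), with mean absolute deviations of 0.451 on chow and 0.235 on high fat. Cyp3a11 (adjusted p = 0.0908) and Plk3 (adjusted p = 0.0947) had larger and Fitm1 (adjusted p = 0.0908) smaller deviations on high fat but did not pass, nor did Atp6v0e2, Cfd, Olfr6, Ctsc and Mical2 (adjusted p of 0.179 to 0.252). In fits that left out 1 strain, Fitm1 passed in 9 of 39 (without BXD61, adjusted p = 0.0425), Atp6v0e2 in 6, Cyp3a11 in 2, and Plk3 and Olfr6 in 1 each. At an unadjusted p under 0.05 there were 1148 of 21765 genes, 266 with wider and 882 with narrower spread, BXD61 included. Chance alone gives about as many in total at that limit, which does not bear on their direction. The lean to narrower spread was not tested, and genes do not vary independently, so no general narrowing is read from it. Of all genes 64.8% had a smaller SD on high fat (59.1% without BXD61). Rtn4 did not pass in 16 of 39 fits that left out 1 strain, with a range of 0.0182 to 0.275 over its alternatives. Without BXD97, BXD80, BXD103 and BXD96, each similar to another strain, neither gene passed (adjusted p = 0.0581 for Cyp2b13), nor without these and BXD100 (0.121). The alternatives for Cyp2b13 ranged from 0.00658 to 0.121.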

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

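The tests on negative controls, similar strains and further probe sets were chosen after the results were seen; the redrawn groupings and the test on the direction of the parental differences were planned.

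Probe sets annotated as negative controls differed between diets: 851 of 5222 passed the diet test. They are not all blank, so a diet difference in them need not be technical. Of the leading principal components of the 2999 negative controls dim over all 81 arrays, component 2 was picked as the one most associated with diet. It held 2.98% of their variance, 90.2% of it associated with diet, and its sign was set to put high fat higher. On it all 41 chow arrays lay below all 40 high-fat arrays. Among the 3007 controls dim on the 78 paired arrays 16.7% passed. That may reflect a technical difference between the arrays of the 2 diets. Of 13 hybridisation and labelling spikes 12 did not pass (BioDn-3 did, 0.09 units, adjusted p = 0.0329). The labelling spikes phe, thr, lys and dap lay 0.0554 to 0.0895 units higher on high fat without passing, and the hybridisation spikes between -0.04 and 0.0861. The median absolute difference of the dim controls was 0.102, so the spikes cannot decide on a shift of that size. The values argue against a technical difference as the whole cause for the 24 genes whose 95% interval, not adjusted over genes, lies beyond the largest control difference. Of these Cyp2b9, Cidea, Cd36 and Csad passed the test against 0.421 units and Saa2 did not (adjusted p = 0.733). Over all genes the spread of diet differences net of error was 1.23 times that of the dim controls, and 1.16 times over the genes within the largest control difference, so technical and dietary parts cannot be told apart there, and the biological effect of diet stays open; a difference in handling that changes transcripts but not controls was not tested.

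Among genes called between the parents, 56.5% were higher in C57BL/6J (95% interval 52.2% to 60.8%). Probes were designed on the C57BL/6J reference, and weaker binding to DBA/2J transcripts may account for part of that excess by a test fixed in advance, which asked for more than 55% and an interval above 50%; it was not met with quantile normalization (54.6%), array weights (54.3%) or without the acinar arrays (55.6%, 49.7% to 61.3%). The 226 genes lower in C57BL/6J need another cause. Further probe sets of called genes shared the sign for 96.7% of those higher and 93.3% of those lower in C57BL/6J (Fisher's exact test, p = 0.309), which leaves the explanation open; a genetic difference in expression is open too, and no genotypes were used here.

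Some strains had similar profiles over 200 strain-variable genes: BXD65 with BXD92a (r = 0.919) and BXD97 (0.789), BXD80 with BXD103 (0.889) and BXD73 (0.792), BXD43 with BXD100 (0.613) and BXD48 with BXD96 (0.597), where the 95th percentile over 861 pairs was 0.273. An exchange of single arrays would break the match between a strain's diets, but 7 of 7 strains with both diets in the sets other than BXD43 and BXD100, which also matched themselves, matched their own other array best; BXD92a has only chow. An exchange of a strain's mice or arrays on both diets would keep that match and is not excluded. Shared ancestry within these sets is a possible explanation that was not tested here. Without BXD97, BXD80, BXD103 and BXD96, 3463 genes differed between strains, and 3442 without BXD100 too.

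Chance can be excluded for the diet and strain counts. For the number of genes that differ by diet, of 100 groupings with diets swapped within strains, 1 (the real one) gave as many as 11693, and the highest other gave 3243. For strain 1 of 100 groupings, the real one, gave as many as 4857, and the highest other gave 14. For the spread, 1 of 100 groupings reached 2 genes, and the highest other gave 1, but this treats similar strains as independent, and 0 genes passed without BXD97, BXD80, BXD103 and BXD96, with or without BXD100, so chance is not firmly excluded there.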

How the results depend on the processing

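Strain names pair the arrays. Without the replicate block 10403 genes differed by diet on all 81 arrays, and 11583 with strain as a random block. On the 78 paired arrays, chosen after seeing the data, these were 10377 and 11584. Each of these 4 fits left 1 list called, as did no other. Diet counts otherwise ranged from 10891 to 12527, except 7280 without the dimmest tercile (fewer genes tested; 104 by at least 0.5) and 54 when tested against the 99th percentile of dim negative controls, 0.421 units (a test chosen after seeing the data), with 54 by at least 0.5. Without the block Moxd1, Dhtkd1, Bckdhb, 6 lists and, of further list members, Abcd2 (adjusted p = 0.0973) did not pass; with the random block these were Dhtkd1 (0.186), Bckdhb (0.0707) and 6 lists. On the 78 arrays they were Dhtkd1, Bckdhb, Abcd2 (0.0835), Trap1 (0.0538) and 6 lists without the block, and Dhtkd1 (0.182), Bckdhb (0.0775) and 6 lists with the random one. None changed another named call. Leaving out each strain gave 11449 to 12019 genes, 155 to 180 by at least 0.5, 5 to 9 lists and 1 (without BXD48, among others) to 5 (without BXD44) genes for the spread, beyond 1.5 times the count in 23 of 39 fits. With an estimated correlation 0 lists passed; the sign-flip test of list means over strains, chosen after seeing the data, called 18. Strain counts ranged from 3442 to 6642. For the parents, array weights gave 1064 genes (642 by at least 0.5), and 297 passed without the DBA/2J chow and BXD63 high-fat arrays, where the lone DBA/2J array is assumed to vary like the rest. Spread counts were 1 with median centring, 1 with BXD strains only, 1 without the acinar arrays, and 0 without the dimmest tercile, without BXD97, BXD80, BXD103 and BXD96, or without these and BXD100. Both of the last fits, chosen after seeing the data, lost the stress list (adjusted p = 0.0591 and 0.113), and the second the acute-phase list (0.0565). The cause was not tested for these changes, except where fewer genes or arrays entered. No named gene or list reversed under any of these. Under the test against negative controls, Saa1, Saa2, Serpina4-ps1, Hamp, Agxt2l1, Moxd1 and Ces6 did not pass, nor did D2hgdh, Dhtkd1, Bckdha, Bckdhb and most named list members, such as Pparg, Ifi44 and G6pc. The deposited tables are identical, so exchanging them gave no other value. Signal near the negative-control level limits 4784 genes whose mean lay below the controls' median.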

Other observations

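The gene lists, the values that set 1 strain apart and the match of strain profiles were planned; the levels in BXD61 were chosen after the results were seen.

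Clock genes changed in opposite directions by diet. Of 22, 12 were higher and 6 lower on high fat: Dbp (0.64 ± 0.10 units), Wee1 (0.60 ± 0.07), Per3 (0.53 ± 0.07), Per2 (0.42 ± 0.05) and Nr1d1 (0.29 ± 0.07) were higher, while Nfil3 (-0.59 ± 0.06), Npas2 (-0.34 ± 0.09), Cry1 (-0.31 ± 0.04), Arntl (-0.24 ± 0.06), Rora (-0.24 ± 0.02) and Clock (-0.16 ± 0.03) were lower. Nfil3 was lower in 36 of 39 strains and Per2 higher in 36. The differences named here reach 0.64 units, and the largest negative-control difference was 0.641. Nfil3 (limma treat, adjusted p = 0.723), Per2, Cry1 and Rora did not pass the test against negative controls. Technical and dietary parts cannot be told apart for them. Dbp, Wee1, Per3, Nr1d1, Npas2, Arntl and Clock were chosen after their values were seen. Camera, which tests for a shift in 1 direction, did not call the list (adjusted p = 0.35), but the sign-flip test of its mean, chosen after seeing the data, did (mean 0.122, higher in 32 of 39 strains, adjusted p = 0.000495). The hour at which each animal was killed was not used here.

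Bile duct and neighbouring lists also held single genes that passed, but 53.7% of all genes did so. The counts below are therefore not read as changes of these lists. Of cholangiocyte markers 5 of 15 were higher and 5 lower, with Ehf at -0.44 ± 0.05, Cdh1 at -0.42 ± 0.06 and Sox9 at -0.28 ± 0.04. Bile acid genes were 4 higher and 5 lower of 22, peroxisomal and omega oxidation genes 4 and 6 of 22, urea cycle and amino acid genes 13 and 7 of 38, with Glul up by 0.24 ± 0.03 in 38 of 39 strains. Cell cycle genes were 8 and 6 of 25, heat shock genes 6 and 2 of 17, and mitochondrial unfolded protein response genes 2 and 2 of 20, with Clpx at -0.33 ± 0.05. Adjusted over the list alone, the counts were 6 and 7 for peroxisomal, 5 and 2 for heat shock, 2 and 1 for unfolded protein response and 6 and 5 for cholangiocyte genes. Endothelial markers were 4 and 1 of 16, neutrophil markers 3 and 2 of 12, erythroid markers 3 and 3 of 11, acinar markers 4 and 2 of 19, adipocyte markers 4 and 4 of 12 and muscle markers 3 and 7 of 13. Adjusted over the list alone, these were 3 and 1 for endothelial, 3 and 4 for erythroid, 3 and 2 for acinar and 5 and 4 for adipocyte markers, and unchanged counts for neutrophil and muscle markers. The mean was positive and camera's direction down for peroxisomal, oxidative phosphorylation and erythroid genes. Median and mean differed in sign for mitochondrial fatty acid oxidation, apolipoprotein, cholangiocyte and erythroid genes. Camera called none of these (smallest adjusted p 0.516). The sign-flip test, chosen after seeing the data, called adipocyte (adjusted p = 0.00084), neutrophil (0.00375) and endothelial markers (0.00753). Their means lay at percentiles 98.76, 99.95 and 74.83 of 10000 random lists, so many random lists shifted as far as the endothelial markers.

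Stab2, a scavenger receptor of liver endothelium, was low in 5 BXD strains (BXD43, BXD51, BXD75, BXD89 and BXD100), with chow scores of 8.11 to 8.73 against a strain mean of 10.7 in C57BL/6J and 10.4 in DBA/2J. The next strain mean was 9.85.

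In 4 genes both arrays of a strain lay at least 1 unit beyond every other array: Ccl20, Cybb and Cd72 high in BXD61, and Serpina3k low in BXD70 (10.7 on high fat against at least 13.4 in other strains). The next 6 widest gaps were for Hamp in BXD81 (7.32 and 6.70 against at least 8.32 in other strains), Guca2b, Ubd and Ccl2 in BXD61, Raet1d in BXD43 and Psmd5 in BXD63, with gaps of 0.742 to 0.999 units. With strain names redrawn among high-fat arrays, 3 of 100 draws reached as many, with 10 genes each. All 3 paired the DBA/2J chow array with the BXD63 high-fat array, and the genes included Cpa1, Cel, Clps and Pnlip. On chow, BXD61 had the highest mean of 7 lists: macrophage, stellate and cholangiocyte genes (1.14, 1.13 and 0.762 units above the chow mean), interferon (0.742), B and plasma cell (0.362), T and natural killer cell (0.357) and cell cycle genes (0.346). It had the lowest of 41 for 11 lists, male-biased (-1.12) and xenobiotic cytochrome P450 genes (-0.93) furthest. Its high-fat array was nearer the mean or beyond it: 0.341 for macrophage (rank 4 of 40), 0.196 for stellate (2), 0.303 for cholangiocyte (1), 0.17 for T and natural killer cell (2), 0.192 for cell cycle (2), 0.111 for interferon (15), -0.0527 for B and plasma cell (28), 0.316 for male-biased (12) and 0.0824 for P450 genes (12). Acute-phase genes ranked 2 on chow (0.902) and 1 on high fat (0.49). Its chow array had the lowest median correlation with other arrays, 0.965 against 0.984 for the next.

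On the 500 genes most variable on chow, 37 of 39 strains had their best high-fat match in their own strain; BXD44 matched BXD98 (0.483, own 0.298) and BXD51 matched BXD45 (0.365, own 0.288).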
